A study of Mus musculus with 24 samples.

How the data were processed

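RNA was sequenced from liver tumours of mice that carry a human MYC transgene under doxycycline control in hepatocytes. The 24 libraries fall into 10 groups by treatment and time after the second dose. The values used here are FPKM per gene as deposited by the authors, who per the submitters' processing notes aligned reads with STAR 2.5 to the mouse genome build mm9 and counted them with HTSeq 0.6.1. No reads or counts were used, so alignment and counting were not repeated. The mouse Myc entry counts reads of the endogenous gene and any reads of the human transgene that align to it, so it is not a measure of the transgene.

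The table held 54532 entries, and each of the 24 samples had its column. In a block of 1025 entries the gene identifiers were shifted against the gene names. There, gene lengths taken by name turned a median of 97.9% of low values into whole reads, and lengths taken by identifier 3.64%, so gene names were used throughout. Left out were 27 entries whose name had become a date, and 102 that shared a symbol with a more abundant entry. Outside the block the identifier and the name differed in 566 entries, for which the name was kept. No genome positions are given, because gene lengths came from an annotation of a newer build than mm9, the build in the notes. These lengths still turned 98.1 to 98.7% of low values in 20 libraries into whole reads. The annotation behind the deposited FPKM is therefore not settled by the notes.

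Whether the values of each column still show single reads was checked. In each library the smallest step between values of genes of known length was taken as 1 read, and a value counted as whole if it lay within 0.02 of a whole number up to 20 reads. In 20 libraries 98.1 to 98.7% of low values were whole. Their read totals by this step were 17.6 to 41.7 M reads, with a median of 34.9 M. In the 4 doxycycline and RMC-4627 libraries 3.69 to 4.09% were whole, so their depth is unknown. Lengths taken by the shifted identifiers gave a like share in the other libraries, 3.64%. Columns computed with other gene lengths could therefore look the same. Below, a library without single-read steps is one in which none were found with the gene lengths used here. Read totals cover counting error only, and reads without molecular identifiers are not independent molecules. Duplicated libraries were looked for in 17 pairs of libraries by a chi-square over genes with at least 20 reads per pair, which was 23.8 to 619 per gene, where a library sequenced again would give about 1.

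Genes with an FPKM of at least 1 in at least 2 libraries were tested, 14373 in all. Values were log2(FPKM + 1), with no further scaling. Differences between groups were tested with limma 3.58.1 (lmFit, then eBayes with trend) in R 4.3.3. All 24 libraries were fitted with 1 mean per group, so that groups of 2 or 3 share an estimate of the spread. All tests were two-sided. Benjamini-Hochberg adjusted p under 0.05 was the threshold. The origin of the replicates (animal or tumour) is not stated in the labels, so p measures the spread between samples. Vehicle was collected at 24 h alone, and the 4, 48 and 72 h groups were compared with it. The description codes of the RMC-6272, RMC-4627 and sorafenib libraries are none of those of the vehicle libraries, so a difference between codes cannot be told apart from treatment. The RMC-4627 codes begin with another letter than all others, so this also holds for RMC-6272 against RMC-4627. The doxycycline libraries share their codes with vehicle. Groups over time were compared with an F test of 3 group means. The single 12 h library of RMC-6272 has no replicate and was not tested.

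Before the data were examined, 55 gene lists with 1240 genes were fixed, of which 1234 genes were found in the table, and 52 lists had at least 5 tested members. Each list was tested in each comparison of 2 groups with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation, and with fry. Members past the threshold were counted over all genes tested and adjusted over the list alone. Genes named one by one followed a rule fixed at the same time. They are the up to 12 largest rises and falls past the threshold, with no overlap between the libraries of both groups and a mean FPKM of at least 5 in the higher group. Unnamed gene models, pseudogenes, Mup genes and antigen receptor segments were left out. Some genes that the rule takes are not used here. Where none passed, the 3 genes with the smallest p are given as values, and for the time tests the up to 10 with the smallest p. Up to 4 members of a list with the smallest p may stand as its examples. Myc, Eif4ebp1, Mtor, Afp, Alb, Mki67, Cd8a and Cd274 are given in each group. Genes outside this rule are named as chosen after their values were seen.

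Fold changes against the shared vehicle libraries correlate with no effect at all. Each correlation is therefore set beside those of 1000 simulated sets of unchanged groups that share a simulated vehicle group (200 per alternative). For these, libraries were drawn from the deviations of all replicated groups about their means, not from the vehicle libraries alone. Overlaps of calls are set beside those of 100 sets. With 3 vehicle libraries the controls could not be divided between the comparisons. The alternatives were a pseudocount of 0.1, no filter on low values, median-ratio scaling, quantile normalization, a replicate block, the description code as a random block (duplicateCorrelation, statmod 1.5.0), a fit of the compared groups alone, and leaving out each replicate in turn. Added after the data were seen were a fit of the 20 libraries with whole reads, limma-voom on the reads recovered from them, the gene lists without the 72 h library rich in blood cell RNA and without RMC-6272 replicate 2 at 24 h, the largest rises in each library, and a comparison of doxycycline with RMC-4627. The tests were tried on simulated data with 200 changed genes in 5 runs. The noise was normal, independent between genes, and had each gene's fitted spread in all groups. At 2-fold, limma called 43.2% of changed genes in 3 against 3 libraries of RMC-6272 at 24 h and vehicle, and 34.8% with the 2 libraries of sorafenib at 24 h. At 4-fold these were 79.0% and 80.2%, and 4.17 to 6.10% of the calls were false. Such noise follows limma's own model, so these shares do not measure the error in the real libraries, where genes vary together. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.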

Results

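The series measured gene expression by RNA sequencing in MYC-driven mouse liver tumours, to compare drugs with vehicle and with switching the MYC transgene off. Vehicle at 24 h had 3 libraries. Doxycycline, which turns the transgene off and was given in drinking water at 100 µg/ml, had 2 libraries at 24 h. RMC-4627 at 10 mg/kg had 2 libraries at 24 h. RMC-6272, also at 10 mg/kg, had 1 library at 12 h and 3 each at 24, 48 and 72 h. Both RMC compounds were given into the peritoneum and are inhibitors of mTOR complex 1, the kinase complex that drives protein synthesis and cell growth. Sorafenib, an oral multikinase inhibitor used in liver cancer, was given at 30 mg/kg per day, with 3 libraries at 4 h and 2 each at 24 and 48 h. Times count from the second dose, and the first was 7 days earlier. For sorafenib, given daily, and doxycycline, given in drinking water, these times alone do not give the length of exposure. The depth of 20 libraries was 17.6 to 41.7 M reads, and that of the doxycycline and RMC-4627 libraries is unknown. Group values below are mean FPKM ± SD over the group's libraries, and fold changes are log2 ± SE from limma.

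RMC-6272 at 24 h was compared with vehicle at 24 h to ask what the compound does to the tumour's expression, including the genes that MYC drives. Genes of cell division fell in 35 of 36 members of the G2/M list, most genes of the lists of ribosome biogenesis and nucleotide metabolism fell (24 of 36 and 20 of 26), and 21 of 38 genes of plasma proteins made by hepatocytes rose. Each of these 4 lists was called by camera, with adjusted p = 0.172, 0.297, 0.172 and 0.365 with an estimated correlation. Of 14373 genes tested, 3120 changed, 1393 higher and 1727 lower, of which 762 and 766 changed at least 2-fold. The libraries of both groups did not overlap in 49.2% of genes, where chance gives 10%. Without vehicle replicate 2, vehicle replicate 3 or RMC-6272 replicate 1 the count was 1944, 1684 and 1852, with the description codes as a random block 1858, and in a fit of the 20 libraries with whole reads, added after the data were seen, 4840.

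In the G2/M list, 35 of 36 genes fell over all genes tested and 36 adjusted over the list alone, with a median of -1.61 (camera adjusted p = 1.62e-24, and adjusted p = 0.172 with an estimated correlation). Aurka, a mitotic kinase, went from 46.2 ± 5.22 FPKM to 12.3 ± 3.46 (-1.85 ± 0.23, adjusted p = 0.000458). Ccna2, cyclin A2, fell by 2.16 and Aurkb by 2.10. In the list of S phase and DNA replication, 39 of 45 fell (42 adjusted over the list alone), with a median of -1.26 (adjusted p = 1.07e-22, and adjusted p = 0.172 with an estimated correlation). Examples are Rpa2, a subunit of the protein that coats single-stranded DNA (-1.67 ± 0.20, adjusted p = 0.000458), Pcna, the sliding clamp (-1.78), and Uhrf1 (-1.80). Mki67, a proliferation marker, went from 22.9 ± 2.57 to 8.13 ± 2.67 FPKM (-1.42, adjusted p = 0.0170).

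MYC-linked ribosome biogenesis fell in 24 of 36 members (28 adjusted over the list alone), with a median of -1.01 (adjusted p = 6.13e-12, and adjusted p = 0.297 with an estimated correlation). Without RMC-6272 replicate 2, 15 fell. Dkc1, which modifies ribosomal RNA, went from 40.4 ± 5.51 to 17.8 ± 5.79 FPKM (-1.18 ± 0.22, adjusted p = 0.00230). In the list of MYC-linked nucleotide, polyamine and one-carbon metabolism, 20 of 26 fell (21 adjusted over the list alone; adjusted p = 1.32e-12, and adjusted p = 0.172 with an estimated correlation). Ppat, the first enzyme of purine synthesis, fell by 1.48 and Rrm1, a subunit of ribonucleotide reductase, by 1.49. Of 39 translation factors, 8 fell (12 adjusted over the list alone; adjusted p = 0.000458, and adjusted p = 0.423 with an estimated correlation), among them Eif4e, which binds the mRNA cap (-1.38 ± 0.31, adjusted p = 0.00631), and Eif2b1 (-1.53). None of 76 cytosolic ribosomal protein genes passed the test in limma over all genes, 0 had an unadjusted p under 0.05, and their median was 0.04 (camera adjusted p = 0.814). The mouse Myc entry, which also counts any transgene reads that align to it, rose from 1.63 ± 0.45 to 6.49 ± 0.18 FPKM (1.52, 95% interval 0.71 to 2.34, adjusted p = 0.0112).

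Biosynthetic and glucose-using pathways fell in part. Of 24 cholesterol synthesis genes, 11 fell (17 adjusted over the list alone), with a median of -1.11 (adjusted p = 3.12e-07, and adjusted p = 0.428 with an estimated correlation). Without RMC-6272 replicate 2, 5 fell. The 11 include Idi1 (-2.38 ± 0.42, adjusted p = 0.00180) and Nsdhl (-2.12), both enzymes of the sterol pathway, and Srebf2 (-0.89), the regulator of the pathway. Among 30 ATF4 targets and amino acid synthesis genes, 11 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.000112, and adjusted p = 0.313 with an estimated correlation). Aldh18a1, an enzyme of proline synthesis, went from 29.6 ± 2.46 to 6.06 ± 1.80 FPKM (-2.14 ± 0.27, adjusted p = 0.000458), and Slc7a1, a carrier of cationic amino acids, fell by 1.84. In glycolysis 6 of 20 fell (10 adjusted over the list alone; adjusted p = 0.00325, and adjusted p = 0.365 with an estimated correlation), led by Pfkp (-1.89) and Hk2, hexokinase 2 (-1.51). The hypoxia list had 6 falls among 21 (9 adjusted over the list alone; adjusted p = 0.00384, and adjusted p = 0.428 with an estimated correlation). Fasn, fatty acid synthase, fell by 1.82, while its list of 20 had 4 falls and 1 rise, Lpin1 (0.92), and was not called.

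Hepatocyte functions rose in part. Of 38 plasma protein genes, 21 rose (25 adjusted over the list alone), with a median of 1.88 (adjusted p = 1.21e-10, and adjusted p = 0.365 with an estimated correlation). Ahsg, which encodes fetuin-A, went from 303 ± 227 to 5159 ± 1364 FPKM (4.45 ± 0.72, adjusted p = 0.00125). Fatty acid oxidation genes rose in 16 of 30 (21 adjusted over the list alone), with a median of 1.71 (adjusted p = 3.28e-10, and adjusted p = 0.365 with an estimated correlation), as with Ehhadh of the peroxisomal pathway (3.92 ± 0.74, adjusted p = 0.00253), Plin2, a lipid droplet protein (3.21), and Acadl (2.04). In gluconeogenesis and glycogen, 7 of 15 rose, also adjusted over the list alone (adjusted p = 0.000962, and adjusted p = 0.428 with an estimated correlation), with Gys2, liver glycogen synthase (3.13), Gckr (2.55) and Pck1 (4.23 ± 1.21, adjusted p = 0.0203). The acute phase list rose in 12 of 22 (13 adjusted over the list alone), with a median of 1.77 (adjusted p = 5.00e-07, and adjusted p = 0.365 with an estimated correlation), for example Cp, ceruloplasmin (3.13), and Lbp (1.70). Autophagy and lysosome genes rose in 10 of 41, also adjusted over the list alone (adjusted p = 4.14e-05, and adjusted p = 0.365 with an estimated correlation), with Ctsa at 1.35. Bile acid and drug metabolism genes rose in 3 of 36 (2 adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.710 with an estimated correlation). Urea cycle and amino acid breakdown had 2 rises and 1 fall among 30, also adjusted over the list alone, and was not called (adjusted p = 0.494). RMC-6272 replicate 2 stood apart in these genes, with a median plasma protein difference from vehicle of 2.79 against 1.73 and 1.12 in the other libraries. Without it 7 plasma protein, 10 fatty acid oxidation, 3 gluconeogenesis and 6 acute phase genes rose, and the bile acid list was not called (adjusted p = 0.300). Alb rose from 1669 ± 1079 to 7411 ± 4842 FPKM, at 12907 in replicate 2 (adjusted p = 0.0423), and Afp, made in fetal liver and in liver tumours, from 1411 ± 410 to 6874 ± 3016 (adjusted p = 0.0129).

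At 24 h MHC class II genes rose in 4 of 10 members (8 rose and 1 fell adjusted over the list alone), with a median of 1.34 (adjusted p = 0.00197, and adjusted p = 0.428 with an estimated correlation). H2-Eb1 rose by 1.56, and Cd74, the invariant chain, rose from 160 ± 116 to 392 ± 97.48 FPKM (adjusted p = 0.0470). MHC class I genes rose in 7 of 22 (7 rose and 1 fell adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.428 with an estimated correlation), with H2-D1 at 1.74 and Tapbp at 1.13. Cd274, the ligand PD-L1, went from 1.59 ± 1.04 to 4.63 ± 1.60 FPKM (1.17, adjusted p = 0.0489), and Cd276 fell by 1.18. ERK pathway output rose in 7 of 19 (8 adjusted over the list alone; adjusted p = 0.000402, and adjusted p = 0.428 with an estimated correlation), including Dusp6, a phosphatase of ERK (2.40 ± 0.53, adjusted p = 0.00580). Without RMC-6272 replicate 2, 2 MHC class II, 4 MHC class I and 4 ERK output genes rose. Markers of other cell types moved with these lists. Macrophage genes rose in 4 of 19, also adjusted over the list alone, as with Trem2 (2.56; list adjusted p = 0.00384, and adjusted p = 0.428 with an estimated correlation). Stellate cell genes rose in 3 of 16 (1 adjusted over the list alone; adjusted p = 0.00265, and adjusted p = 0.382 with an estimated correlation), as with Pdgfrb (1.79), and in 1 without RMC-6272 replicate 2. Of 7 T cell genes none passed in limma over all genes and 0 had an unadjusted p under 0.05 (median 0.20), and Cd8a was under the filter, at 0.0838 FPKM in vehicle and 0.122 with RMC-6272.

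By size, the largest rises at 24 h after Apoa4 (4.88 ± 1.59, adjusted p = 0.0371; 829 ± 1230 against 15.9 ± 18.9 FPKM), Ahsg and Pck1 were in Vnn1, Pzp, Fgl1, Ehhadh, Adh1, Pdk4, Hamp, Fabp2 and F11, from 4.06 down to 3.52. Several of them encode proteins that hepatocytes secrete, such as the clotting factor F11 (3.52 ± 0.43, adjusted p = 0.000458). In 9 of these 12 genes RMC-6272 replicate 2 was the highest of its group, and without it Apoa4, Pck1, Fgl1, Hamp and Fabp2 did not pass (adjusted p = 0.172, 0.109, 0.0624, 0.170 and 0.0880). The largest falls were in Crabp2, which binds retinoic acid (-4.35 ± 0.66, adjusted p = 0.00105), Phlda2 (-3.70), and Mthfd2, a mitochondrial enzyme of one-carbon metabolism (-3.63 ± 0.45, adjusted p = 0.000458; 1.41 ± 0.32 against 28.7 ± 3.17 FPKM). L1td1 and Slc16a3, a lactate carrier, each fell by 3.54, and Ccnb1ip1, Epop, Smpdl3b, Rpp25, Gstm3, Fam81a and Nrtn fell by 2.99 down to 2.54. Tfrc, the transferrin receptor, fell by 2.48. Eif4ebp1, whose protein mTOR complex 1 phosphorylates, was at 44.9 FPKM against 79.9 (-0.75, adjusted p = 0.0726), and Mtor at 7.18 against 5.27 (0.38, adjusted p = 0.538), neither past the test.

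**Figure D1:**
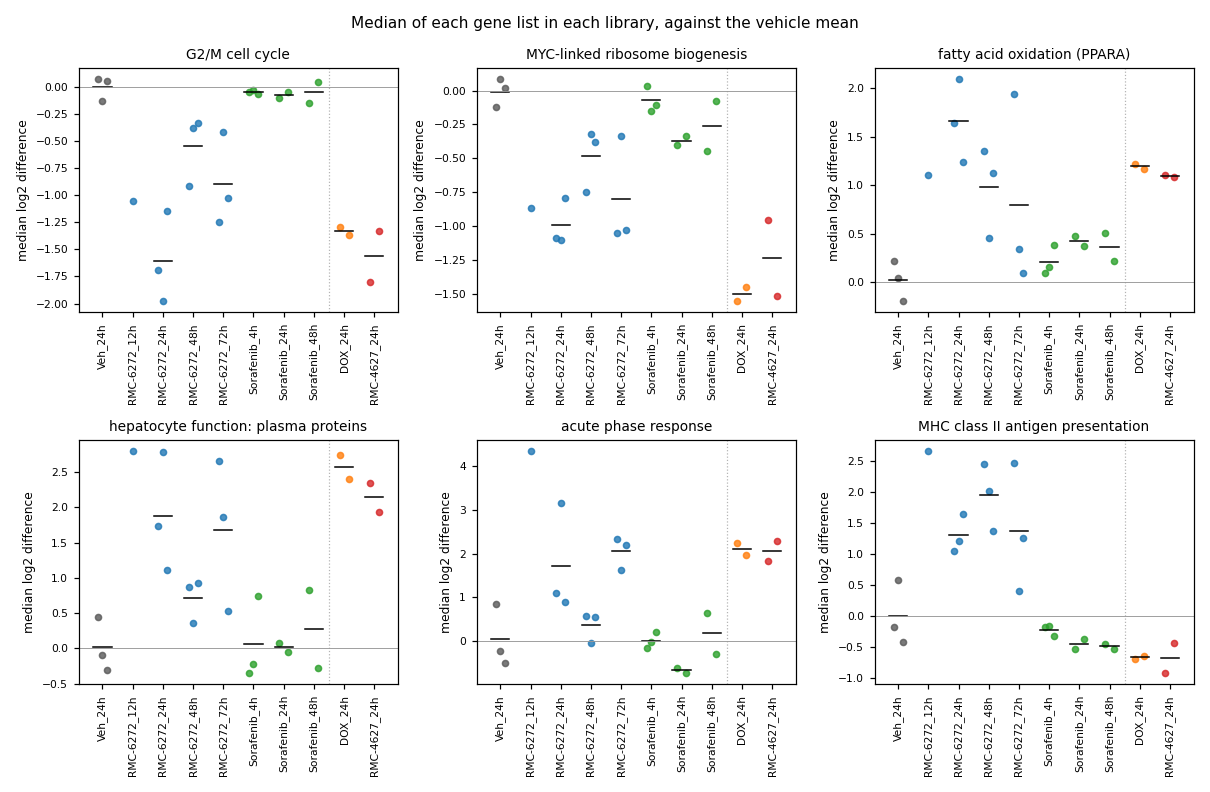
Median log2 difference from the vehicle mean of the genes of each list (vertical axis), with 1 point per library by group (horizontal axis), bars at the group mean of the library medians, and a dotted line before the 4 libraries whose values were made in another way. Taken over fold changes, the G2/M median was -1.61 for RMC-6272 at 24 h, and the 12 h library lay at -1.06.

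RMC-6272 at 48 and 72 h was compared with the 24 h vehicle to follow the response. At 48 h 9 genes changed, 4 higher and 5 lower, and 2117 had an unadjusted p under 0.05. Igfbp5, which binds insulin-like growth factors, fell from 17.1 ± 5.88 to 2.52 ± 1.71 FPKM (-2.42 ± 0.32, adjusted p = 0.00962). L1td1 fell (-3.10 ± 0.44, adjusted p = 0.0164), Cd52, a leukocyte surface protein, rose (1.47 ± 0.26, adjusted p = 0.0466), and so did the antisense transcript Rap1gapos (1.69 ± 0.30, adjusted p = 0.0466).

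No list had a member past limma's threshold over all genes at 48 h, and 192 of the 1130 list genes had an unadjusted p under 0.05. Adjusted over the list alone, 9 of 10 MHC class II genes rose and 1 fell, with a median of 1.91 (camera adjusted p = 1.70e-10, and adjusted p = 0.181 with an estimated correlation); H2-Ab1 was at 2.31 and Ctss at 2.23. Of 30 fatty acid oxidation genes 4 rose adjusted over the list alone (camera adjusted p = 1.37e-08, and adjusted p = 0.391 with an estimated correlation), and of 19 macrophage genes 6 (adjusted p = 4.77e-06, and adjusted p = 0.301 with an estimated correlation). The G2/M median was -0.57 with no member past the test over the list alone either and 12 of 36 at unadjusted p under 0.05 (camera adjusted p = 1.70e-10, and adjusted p = 0.318 with an estimated correlation), and that of ribosome biogenesis -0.46 (adjusted p = 1.13e-07, and adjusted p = 0.301 with an estimated correlation). The count at 48 h was 0 without vehicle replicate 1 or 3 (1855 and 1360 at unadjusted p under 0.05), 1 without 48 h replicate 1 and 82 without 48 h replicate 3. It was 1 with a pseudocount of 0.1, 0 with the codes as a random block (898 at unadjusted p under 0.05) and 15 in the fit of 20 libraries.

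At 72 h 1672 genes changed, 750 higher and 922 lower, 493 and 282 of them at least 2-fold (656 higher and 897 lower after median-ratio scaling, and 574 and 1283 after quantile normalization). G2/M genes fell in 17 of 36 (26 adjusted over the list alone), with a median of -0.91 (adjusted p = 7.92e-13, and adjusted p = 0.351 with an estimated correlation). S phase genes fell in 19 of 45 (28 adjusted over the list alone; adjusted p = 5.54e-12, and adjusted p = 0.351 with an estimated correlation), such as Chaf1a (-1.01). Ribosome biogenesis fell in 15 of 36 (22 adjusted over the list alone; adjusted p = 3.53e-11, and adjusted p = 0.351 with an estimated correlation). Nucleotide metabolism fell in 14 of 26 (17 adjusted over the list alone; adjusted p = 2.73e-10, and adjusted p = 0.351 with an estimated correlation). Dkc1 of ribosome biogenesis was at -1.39 ± 0.22 and Ppat of nucleotide metabolism at -1.43 ± 0.22 (adjusted p = 0.00838 each). Of 24 cholesterol synthesis genes 3 fell (6 adjusted over the list alone; adjusted p = 0.000542, and adjusted p = 0.430 with an estimated correlation). The acute phase list rose in 12 of 22 (18 adjusted over the list alone), with a median of 1.92 (adjusted p = 3.61e-08, and adjusted p = 0.351 with an estimated correlation), for example the complement gene C4b (2.11 ± 0.45, adjusted p = 0.0148). Plasma protein genes rose in 9 of 38 (21 adjusted over the list alone; adjusted p = 5.36e-10, and adjusted p = 0.355 with an estimated correlation), and MHC class II genes in 6 of 10 (7 adjusted over the list alone; adjusted p = 0.000528, and adjusted p = 0.355 with an estimated correlation).

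Among blood cell lists at 72 h, neutrophil genes rose in 4 of 10 (9 adjusted over the list alone; adjusted p = 0.000130, and adjusted p = 0.355 with an estimated correlation). T cell genes rose in 3 of 7 (4 adjusted over the list alone; adjusted p = 0.00484, and adjusted p = 0.355 with an estimated correlation). Genes of red cells and their precursors rose in 1 of 9, Klf1 (1.23; adjusted over the list alone 6 rose and 1 fell; adjusted p = 0.0124, and adjusted p = 0.430 with an estimated correlation). S100a9 (5.04 ± 1.28, adjusted p = 0.0251) and S100a8 (4.42) were highest in 72 h replicate 3, where S100a8 was at 842 FPKM against at most 24.1 in the other 19 libraries with whole reads. Without 72 h replicate 3 their rises were 2.56 and 2.07. That library had the lowest depth, 17.6 M reads, with 6.24% of FPKM in globin genes. Without it 488 genes changed, and over all genes 4 G2/M, 8 S phase, 3 ribosome biogenesis, 7 nucleotide, 8 plasma protein, 2 acute phase, 1 MHC class II, 1 cholesterol synthesis and 2 neutrophil genes passed in limma. None of the 7 T cell and 9 red cell genes did, with 3 and 2 at unadjusted p under 0.05, and the red cell list was not called (adjusted p = 0.229). The count was 108 and 390 without vehicle replicate 1 or 3, and 3404 without 72 h replicate 2, and without vehicle replicate 2 it kept 688 of the 1672 genes. With the codes as a random block it was 150, with no filter 791, in the fit of 20 libraries 3646, and 0 in a fit of the compared groups alone, where 3170 genes had an unadjusted p under 0.05.

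By size at 72 h, after S100a9 and S100a8, the largest rises were in Pck1 and Lrg1 (4.36 each), Fgl1 (4.21), Orm1 (4.04), Hamp, which encodes the iron hormone hepcidin (3.86), Lcn2 (3.84), Itih4 (3.68), Serpina3n (3.46), Sult1a1 (3.36) and the neutrophil gene Retnlg (3.33). In 72 h replicate 3, the library rich in blood cell RNA, Lcn2, Serpina3n and Retnlg were at 518, 232 and 114 FPKM, with group values of 203 ± 275, 120 ± 98.5 and 39.4 ± 64.3. Without it S100a9, S100a8 and Hamp passed, and the other 9 of these rises did not, with Lcn2 at adjusted p = 0.139 and Retnlg at 0.0535. Among these, Pck1, Lrg1, Fgl1, Orm1, Itih4 and Sult1a1 were at 5.01, 4.40, 4.39, 4.15, 4.16 and 3.79 without it, no smaller than with it. Lcn2, Serpina3n and Retnlg were at 2.52, 2.82 and 1.59. Replicate 3 was the highest of its group in 5 of the 12 rises. The largest falls were in Bmp8b (-3.21 ± 0.54, adjusted p = 0.00838), Crabp2 (-3.06), L1td1 (-2.92), Slc7a8 (-2.04), Kif20a, a mitotic kinesin (-2.02), Aldh18a1 (-1.98), Idi1 (-1.96), Nr1h5 (-1.94) and Mthfd2 (-1.84). Rasal1, Skp2 and Dusp9 fell by 1.73, 1.69 and 1.66. Between 24 and 72 h the called genes overlapped in 434 higher and 687 lower, where independent lists would share 72.7 and 111 and 100 sets of unchanged groups shared at most 2 and 24. The vehicle libraries were in common, so part of the excess may come from them. The unchanged groups hold no effect to call and cannot show how large that part is.

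A test of 24, 48 and 72 h against each other found 2 genes that differed, Zim1 and Rpl21-ps10, and 2347 at unadjusted p under 0.05. Without 72 h replicate 1 it found 922. Without the other libraries it found 62 (24 h replicate 2), 13 (24 h replicate 3), 12 (72 h replicate 2), 3 (48 h replicate 1 or 72 h replicate 3, with Zim1 and without Rpl21-ps10), 1 (24 h replicate 1, another gene) and 0 in limma (48 h replicate 2 or 3, with 1629 and 1704 at unadjusted p under 0.05). With a pseudocount of 0.1 it found 2 other genes, and Zim1 and Rpl21-ps10 did not pass (adjusted p = 0.0814 and 0.106). Among the genes with the smallest p, Aurka was at 12.3, 35.1 and 25.7 FPKM and Stmn1, which regulates microtubules, at 9.83, 27.1 and 31.3 (adjusted p = 0.0702 each, not past the test). Myc was at 6.49 ± 0.18, 3.61 ± 1.86 and 5.84 ± 3.06 FPKM and Mki67 at 8.13, 17.9 and 17.3.

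Sorafenib was compared with vehicle at 4, 24 and 48 h as the drug in clinical use. limma found 0 genes past the threshold at 4 h, 1 at 24 h and 0 at 48 h, with 163, 321 and 131 at unadjusted p under 0.05. The gene at 24 h was the microRNA gene Mir1950 (1.99 ± 0.26, adjusted p = 0.00952; 3.97 ± 0.17 against 0.263 ± 0.231 FPKM). It was not past the test without vehicle replicate 3, either sorafenib library, with a pseudocount of 0.1, or with the codes as a random block (unadjusted counts of 329, 126, 202, 311 and 218). Genes with the smallest p next to it were Ccl2, a chemokine (-1.17, adjusted p = 0.275), and Dram1 (-1.47, adjusted p = 0.514). At 4 h they were Kctd15 (-1.20, adjusted p = 0.395), Pdzrn3 (-0.81, adjusted p = 0.798) and Eda2r (1.56), and at 48 h Pdzrn3 (-0.83), Igfbp5 (-1.29) and Cyp39a1 (0.90), the last 4 values at adjusted p = 1. At 4 h 1 gene passed without sorafenib replicate 3.

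Camera called 16, 17 and 16 lists at 4, 24 and 48 h of sorafenib, none of them with an estimated correlation or with fry. No member of any list passed over all genes in limma, and 15, 23 and 9 of 1130 list genes had an unadjusted p under 0.05. Adjusted over the list alone, none of the interferon and extracellular matrix genes passed. The interferon response had medians of -0.49, -0.63 and -0.28 (adjusted p = 4.96e-20, 5.95e-14 and 0.000167, and adjusted p = 0.397, 0.363 and 0.749 with an estimated correlation). Extracellular matrix genes had -0.41, -0.29 and -0.34 (adjusted p = 2.03e-10, 0.00230 and 5.76e-05, and adjusted p = 0.449, 0.676 and 0.681 with an estimated correlation). Fatty acid oxidation had positive medians, 0.18, 0.43 and 0.38 (adjusted p = 0.0132, 0.000647 and 6.73e-05, and adjusted p = 0.822, 0.676 and 0.773 with an estimated correlation). The G2/M list was not called at any time, and Mki67 was at 20.04, 23.3 and 23.6 FPKM against 22.9 in vehicle, a difference of 0.02 at 24 h (95% interval -0.90 to 0.95). Over the 3 times Mir1950 alone differed in limma's F test, with 172 genes at unadjusted p under 0.05. No gene differed without either 24 h library (129 and 145 at unadjusted p under 0.05), and 2 did without 4 h replicate 3.

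RMC-6272 and sorafenib were set against each other at 24 h. Of 1228 genes that differed, 535 were higher and 693 lower with RMC-6272. G2/M genes were lower in 33 of 36 (36 adjusted over the list alone), with a median of -1.64 (adjusted p = 4.88e-27, and adjusted p = 0.188 with an estimated correlation). S phase genes were lower in 28 of 45 (38 adjusted over the list alone; adjusted p = 2.68e-23, and adjusted p = 0.188 with an estimated correlation), and nucleotide metabolism genes in 12 of 26 (17 adjusted over the list alone; adjusted p = 4.78e-11, and adjusted p = 0.222 with an estimated correlation). Stmn1 was at 9.83 ± 2.21 against 61.2 ± 2.03 FPKM (-2.54 ± 0.32, adjusted p = 0.00205), Aurka at -1.83 and Aldh18a1 at -2.20 (adjusted p = 0.00205 each). Higher with RMC-6272 were 12 of 22 acute phase genes (17 adjusted over the list alone), with a median of 2.53 (adjusted p = 1.26e-10, and adjusted p = 0.222 with an estimated correlation). So were 8 of 38 plasma protein genes (21 adjusted over the list alone; adjusted p = 2.31e-11, and adjusted p = 0.295 with an estimated correlation) and 6 of 10 MHC class II genes (9 adjusted over the list alone; adjusted p = 2.01e-06, and adjusted p = 0.289 with an estimated correlation). MHC class I genes were higher in 4 of 22 (10 higher and 1 lower adjusted over the list alone; adjusted p = 8.16e-05, and adjusted p = 0.295 with an estimated correlation). ERK output genes were higher in 8 of 19, also adjusted over the list alone (adjusted p = 1.89e-06, and adjusted p = 0.289 with an estimated correlation). RMC-6272 replicate 2 stood apart in liver genes here too, with a median plasma protein difference from vehicle of 2.79 against 1.73 and 1.12. Without it 7 acute phase, 1 plasma protein, 3 MHC class II, 1 MHC class I and 3 ERK output genes were higher, and 18 G2/M, 16 S phase and 6 nucleotide genes lower. In the full comparison Cd274 (1.63, adjusted p = 0.0363) and Myc (1.89, adjusted p = 0.0172) were higher.

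Among single genes the widest gaps to sorafenib were in Orm1 (7.12 ± 1.19, adjusted p = 0.00588; 430 ± 596 against 0.436 ± 0.215 FPKM), Serpina3k (6.59), Lrg1 (5.56), Pck1 (5.39), Hp (5.29), Fgl1 (5.16), Apoa5 (4.99), Lcn2 (4.99), Saa1 (4.81), Wfdc21 (4.66), Serpina3m (4.60) and Adh1 (4.53). All 12 were highest in RMC-6272 replicate 2, with Orm1 at 1117, Serpina3k at 1278 and Hp at 3681 FPKM, and without it Orm1, Fgl1, Saa1 and Adh1 passed and the other 8 did not. Lower were Tff3 (-3.01), Mthfd2 (-2.94 ± 0.50, adjusted p = 0.00611), Crabp2 (-2.91), L1td1 (-2.79), Nrtn and Phlda2 (-2.73 each), Smpdl3b (-2.69), Fam81a (-2.61), Llcfc1 (-2.45), Rac3 (-2.44) and Fcna (-2.35). The count rests on both sorafenib libraries. It was 1 and 10 without sorafenib replicate 1 or 2, and 344 and 515 without RMC-6272 replicate 1 or 2. It was 2304 with the codes as a random block, 2687 in a fit of the compared groups alone, 778 with no filter on low values, and 2550 in the fit of 20 libraries.

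Doxycycline and RMC-4627 were compared with vehicle to set MYC withdrawal and an mTOR complex 1 inhibitor beside each other. The values in their 4 libraries were made in another way than those of the other 20, as 3.69 to 4.09% of their low values were whole reads against 98.1 to 98.7%. The gene model Gm23935 took 0.132 to 0.321% of FPKM in the 4 libraries and 2.48 to 18.4% in the 20, and mitochondrial mRNA 1.54 to 2.88% and 3.37 to 10.4%. Of 2944 genes with at least 10 FPKM in all 20 libraries, 18 lay under 0.1 FPKM in all 4. No vehicle library lacks single-read steps as these 4 do, so treatment and processing cannot be told apart in any comparison below that sets them against other libraries.

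With doxycycline 7749 genes differed from vehicle, 2740 higher and 5009 lower, and the median of all genes was -0.29 (-0.11 after median-ratio scaling and -0.04 after quantile normalization). The counts were 3518 higher and 4152 lower after median-ratio scaling, and 3732 and 3870 after quantile normalization. Plasma protein genes rose in 26 of 38 (28 adjusted over the list alone), with a median of 2.57 (adjusted p = 1.71e-07, and adjusted p = 0.861 with an estimated correlation). Bile acid and drug metabolism genes rose in 21 of 36, also adjusted over the list alone (adjusted p = 1.30e-05, and adjusted p = 0.874 with an estimated correlation). Acute phase genes rose in 15 of 22, also adjusted over the list alone (adjusted p = 7.75e-06, and adjusted p = 0.760 with an estimated correlation), with Saa1, serum amyloid A, at 1199 ± 386 against 2.33 ± 2.53 FPKM (8.71 ± 0.91, adjusted p = 5.79e-07). G2/M genes fell in 25 of 36 and rose in 2, also adjusted over the list alone (adjusted p = 0.000897, and adjusted p = 0.874 with an estimated correlation). S phase genes fell in 29 of 45 and rose in 5, also adjusted over the list alone (adjusted p = 0.00318, and adjusted p = 0.874 with an estimated correlation). Ribosome biogenesis fell in 22 of 36, also adjusted over the list alone (adjusted p = 0.000370, and adjusted p = 0.861 with an estimated correlation). Mki67 fell by 2.73 and Alb rose by 4.24. Beside these, muscle markers rose in 5 of 7 (median 3.51, adjusted p = 0.0373 with an estimated correlation) and adipose and mesothelium markers in 7 of 8 (median 1.48, adjusted p = 0.0287 with an estimated correlation), both also adjusted over the list alone. Other large rises were in the muscle genes Tnnt2 (8.20), Mb, listed at 0 in all 3 vehicle libraries, Myh6, Des, Ttn and Acta1, and in Uox, urate oxidase (7.55), Pdk4 (7.33), Bhmt (7.17), Saa2 (7.13) and Fgl1 (7.09). The largest falls were in Cct2, which was listed at 0 in both doxycycline libraries against 262 ± 13.3 FPKM, Sephs2, Phb, also listed at 0 in both against 181 ± 37.3, Clta, Dlk1 (-6.25), Mir5125, Ndufa10, Esd, Kpna2 (-5.97), Ntmt1, Kat2a and Gcdh. Cct2, Phb and Esd were listed at 0 in both RMC-4627 libraries too, and were at 162, 103 and 57.0 FPKM with RMC-6272 at 24 h. Their values of 0 are therefore not read as an effect of doxycycline.

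With RMC-4627 7371 genes differed, 2553 higher and 4818 lower, 4277 in a fit of the compared groups alone. After median-ratio scaling 3385 were higher and 3870 lower, and after quantile normalization 3679 and 3517. The median of all genes was -0.29 (-0.09 after median-ratio scaling and -0.002 after quantile normalization). G2/M genes fell in 27 of 36 and rose in 2 (28 and 2 adjusted over the list alone; adjusted p = 0.000171, and adjusted p = 0.918 with an estimated correlation), and ribosome biogenesis fell in 24 and rose in 1 of 36 (25 and 1 adjusted over the list alone; adjusted p = 0.000524, and adjusted p = 0.918 with an estimated correlation). Plasma protein genes rose in 21 of 38, also adjusted over the list alone (adjusted p = 3.23e-06, and adjusted p = 0.918 with an estimated correlation), and acute phase genes in 14 of 22 (15 adjusted over the list alone; adjusted p = 8.13e-06, and adjusted p = 0.918 with an estimated correlation), with Saa1 at 8.33 ± 0.91 (adjusted p = 1.03e-06). Beside them rose 6 of 7 muscle markers (median 4.88) and 6 of 8 adipose and mesothelium markers (median 1.95; adjusted p = 0.0190 with an estimated correlation for each), also adjusted over the list alone. Both libraries differed from each other: Mki67 was at 2.05 and 12.2 FPKM and Myc at 0.440 and 3.62. Other named rises were Myh6, Acta1, Nppa, Tnnt2, Mb and Ttn of muscle, and Saa2 (7.31), Pam (6.63), Tdo2 (6.46) and Cyp3a11 (6.41). Falls were in Cct2, Sephs2, Phb, Haao (-7.16), Clta, Kpna2 (-6.44), Mir5125, Dlk1 (-6.22), Ndufa10, Esd, Pkm, a pyruvate kinase (-5.97), and Mapk3 (-5.93). Of these, Cct2, Phb and Esd were listed at 0 in both RMC-4627 libraries as in both doxycycline libraries. Their values of 0 are not read as an effect of RMC-4627 either. Doxycycline and RMC-4627 shared 1830 higher and 3922 lower genes of those called (487 and 1679 if independent), with the vehicle libraries in common and values unlike those of vehicle in both. In 100 sets of unchanged groups none were shared, but with no effect to call these sets cannot judge overlaps of long lists.

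The RMC compounds were compared at the same dose and time, 10 mg/kg and 24 h. Between them 6743 genes differed, 4552 higher and 2191 lower with RMC-6272 (3072 in a fit of the compared groups alone), with a median of all genes of 0.33. The balance depends on the scaling, with 3543 higher and 3039 lower after median-ratio scaling and 3122 and 3494 after quantile normalization. MHC class II genes were higher with RMC-6272 in 8 of 10 (9 adjusted over the list alone), with a median of 2.10 (adjusted p = 0.0384, and adjusted p = 0.933 with an estimated correlation), and Cd74 was at 392 ± 97.48 against 5.38 ± 4.78 FPKM (6.15 ± 0.58, adjusted p = 2.43e-07). Cholesterol synthesis genes were lower in 11 of 24 and higher in 1, also adjusted over the list alone (adjusted p = 0.00714, and adjusted p = 0.933 with an estimated correlation). FOXO targets were lower in 9 of 20, also adjusted over the list alone (adjusted p = 0.00699, and adjusted p = 0.261 with an estimated correlation). Muscle markers were lower in 4 of 7 and adipose and mesothelium markers in 6 of 8, also adjusted over the list alone (adjusted p = 0.0238 each with an estimated correlation). In the G2/M list 5 were higher and 8 lower, also adjusted over the list alone, with a median of -0.01, and it was not called. Myc was higher with RMC-6272 (1.54, 95% interval 0.63 to 2.45, adjusted p = 0.00738). Differences not past the test were Mki67 0.48 (-0.44 to 1.41), Alb -1.80 (-3.51 to -0.08; adjusted p = 0.0786), Afp 0.55 (-0.82 to 1.92), Eif4ebp1 0.50 (-0.18 to 1.18), Mtor -0.47 (-1.42 to 0.47) and Cd274 0.78 (-0.18 to 1.73).

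Single genes with the largest gaps between the compounds were mostly those in which the 4 libraries stand apart from the other 20. Higher with RMC-6272 were Cct2 (listed at 0 in both RMC-4627 libraries), Sephs2, Clta, Phb, Chmp2a, Haao, Dlk1 (6.36), Rn7sk, a small nuclear RNA, Mir5125, Cope and Esd. Lower were the muscle genes Myh6 (-8.45), Acta1, Nppa, Tnnt2, Mb, Ttn, Tnnt3, Tnni3, Atp2a1, Tcap and Myh8, and Pam (-5.79).

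Against doxycycline at 24 h, RMC-6272 differed in 7350 genes, 4906 higher and 2444 lower, also with a median of all genes of 0.33. After median-ratio scaling 3949 were higher and 3236 lower, and after quantile normalization 3457 and 3620. Cholesterol synthesis genes were lower with RMC-6272 in 14 of 24 and higher in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.00247, and adjusted p = 0.927 with an estimated correlation). Bile acid and drug metabolism genes were lower in 12 of 36 and higher in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00684, and adjusted p = 0.927 with an estimated correlation). MHC class II genes were higher in 9 of 10, also adjusted over the list alone (adjusted p = 0.0447, and adjusted p = 0.927 with an estimated correlation). Muscle and adipose markers were lower in 5 of 7 and 5 of 8, also adjusted over the list alone (adjusted p = 0.0457 each with an estimated correlation). Cyp2c29, a drug-metabolising enzyme, was at 5.20 ± 7.58 against 460 ± 48.5 FPKM (-6.98 ± 1.54, adjusted p = 0.00117), and Thrsp, a regulator of lipid synthesis, at -5.90. Mb, Tnnt2, Myh6, Ttn, Acta1, Nppa, Myh1, Atp2a1, Tnni3 and Myl4 of muscle were lower. Sephs2, Cct2 (listed at 0 in both doxycycline libraries), Clta, Phb, Dlk1 (6.39), Esd, Chmp2a, Mir5125, Bhmt2 (5.73), Ndufa10, Mt2, a metallothionein (5.69), and Cuta were higher. Myc (2.34, adjusted p = 0.000246) and Mki67 (1.31, adjusted p = 0.0199) were higher and Alb lower (-2.07, adjusted p = 0.0423).

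**Figure D2:**
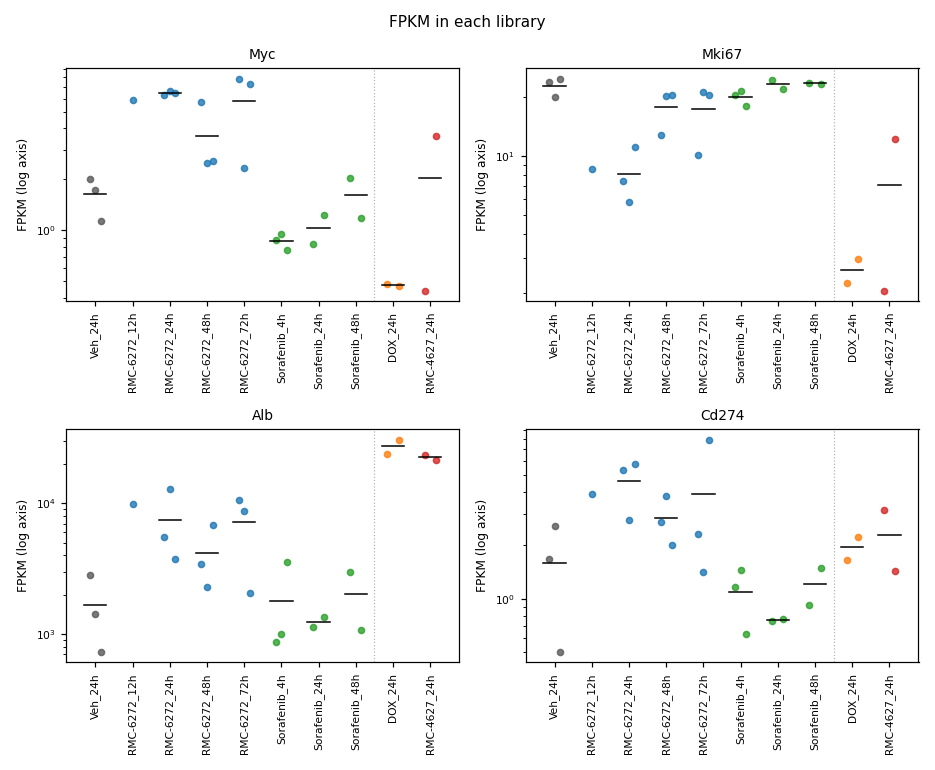
FPKM (log axis) of Myc, Mki67, Alb and Cd274 in each library by group, with 1 point per library, bars at the group mean, and a dotted line before the doxycycline and RMC-4627 libraries. Mki67 averaged 22.9 FPKM in vehicle and 8.13 with RMC-6272 at 24 h.

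How far the drug responses share direction was measured across genes, which are not independent replicates. The log2 changes against vehicle of RMC-6272 at 24 h correlated with those of doxycycline at r = 0.430, of RMC-4627 at r = 0.454 and of sorafenib at 24 h at r = 0.226. Unchanged groups with a shared simulated vehicle gave mean r of 0.434, 0.441 and 0.430, with 95% ranges reaching up to 0.881, 0.888 and 0.886. None of the 3 correlations lay above these ranges. The simulation drew on deviations in all replicated groups, where RMC-4627 libraries correlated at r = 0.758 and vehicle libraries at 0.962 to 0.976. Its ranges of r and covariance may thus differ from those of these vehicle libraries, and they cannot decide whether the responses are shared. Without 1 library r was 0.335 to 0.502, 0.360 to 0.528 and 0.154 to 0.384, and for sorafenib 0.384 was the value without vehicle replicate 1. The covariance was 0.458, 0.455 and 0.0539, with simulated ranges up to 0.269, 0.278 and 0.283. Differences from the simulated means were 0.383, 0.378 and -0.0211. The covariance with doxycycline lay within the simulated range without vehicle replicate 2 or 3 or doxycycline replicate 2 (0.426, 0.403 and 0.459, with ranges up to 0.436, 0.503 and 0.467), and that with RMC-4627 without vehicle replicate 3 (0.401, up to 0.414). With 3 vehicle libraries the controls could not be divided, and part of the excess for doxycycline and RMC-4627 may come from shared controls. RMC-6272 at 24 h shared 379 higher and 1220 lower genes with doxycycline (266 and 602 if independent) and 408 and 1183 with RMC-4627 (247 and 579 if independent). In 100 sets of unchanged groups either pair shared at most 5 genes. Such groups hold no effect to call, so they give no reference for overlaps between long lists of calls.

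**Figure D3:**
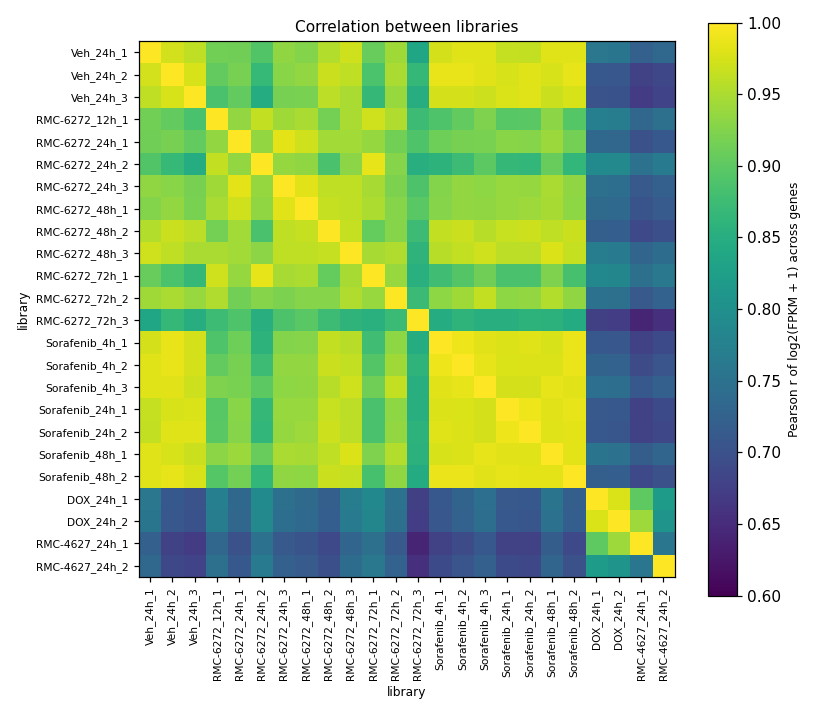
Pearson r of log2(FPKM + 1) between all 24 libraries, shown as colour, with libraries in the order of their groups on both axes. Within the 20 libraries with whole reads r was 0.836 to 0.991, and between these and the 4 doxycycline and RMC-4627 libraries 0.642 to 0.790.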

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

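The time tests were planned; the tests of the 3 patterns weighed here and the limits used for the 12 h library were chosen after the results were seen. Between 24, 48 and 72 h of RMC-6272, Zim1 differed, at 2.02, 0.642 and 0.317 FPKM (adjusted p = 0.0487). Rpl21-ps10, a pseudogene whose reads other genes can share, was at 0.766, 0.844 and 3.05 FPKM (adjusted p = 0.0487). Neither passed with a pseudocount of 0.1 (adjusted p = 0.0814 and 0.106), with median-ratio scaling or in the fit of 20 libraries. Between 4, 24 and 48 h of sorafenib, Mir1950 differed, listed at 0 in the 4 h libraries and at 3.97 and 1.00 FPKM later (adjusted p = 0.00587), and did not pass with a pseudocount of 0.1 (adjusted p = 0.455).

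The single RMC-6272 library at 12 h entered no comparison. In 25 lists its median against the vehicle mean (log2) lay outside the range of the vehicle libraries and under the 0.1 or over the 99.9 percentile of 10000 random lists of the same size and similar abundance. Random lists ignore that genes of a list vary together, so the percentiles cannot tell an effect at 12 h from the make-up of 1 sample. Lower lists were G2/M (-1.06), MYC-linked ribosome biogenesis (-0.87), S phase (-0.84), nucleotide, polyamine and one-carbon metabolism (-0.83), p53 targets (-0.82), which include genes of cell division, and glycolysis (-0.58). Higher lists of liver function were the acute phase response (4.35), plasma proteins (2.80), bile acids and drug metabolism (2.15), gluconeogenesis and glycogen (1.59), fatty acid oxidation (1.11), urea cycle and amino acid breakdown (1.09) and hepatocyte transcription factors (0.81). Higher lists of immunity and stroma were MHC class II (2.66), dendritic cells (2.07), macrophages (1.58), MHC class I (1.02), immune checkpoint genes (0.92), stellate cells (0.89), neutrophils (0.80) and interferon response (0.42). Red blood cells and precursors (2.35), ERK pathway output (0.68), the unfolded protein response (0.53), and autophagy and lysosome (0.34) were higher too. With 1 library no spread was measured.

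The first pattern is that many genes, 7749 and 7371, differed between vehicle and the doxycycline and RMC-4627 libraries. Among genes with a mean of at least 1 FPKM in the other 20 libraries, 80 of 161 small RNA genes (49.7%) lay under 0.1 FPKM in all 4 of these libraries, against 125 of 10747 protein-coding genes (1.16%), so values made in another way may account for part of the difference. Doxycycline and RMC-4627, both without single-read steps, differed from each other in 1675 genes. How much the treatments contribute stays open, because no vehicle library lacks these steps.

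The second pattern is striated muscle genes in the doxycycline and RMC-4627 libraries. Of 18 muscle genes, 17 lay above all 20 other libraries in all 4, and Myl2 did not. Heart muscle in the samples would keep Tnnt2 and Myh6 near 1 ratio, but the highest ratio was 855 times the lowest, and 11.1 times without RMC-4627 replicate 2. Because 18 of 2944 genes with at least 10 FPKM in all 20 other libraries lay under 0.1 FPKM in all 4, single values of these libraries decide nothing. Muscle tissue, the way the values were made and the treatments cannot be told apart: all 4 libraries differ from vehicle both in how their values were made and in treatment, 2 with doxycycline and 2 with RMC-4627.

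The third pattern is blood cell genes in RMC-6272 at 72 h, replicate 3. Against the vehicle mean, genes of immature blood cells had a median of 4.77 (log2), where the other 19 libraries with whole reads lay between -0.0210 and 0.719, and mature B cell markers had 0.0137 (-0.299 to 0.0942 in the others). Elane and Mpo of neutrophil precursors were at 26.2 FPKM each, Slc4a1 and Alas2 of red cells at 82.4 and 218, Pf4 of platelets at 144 and S100a8 at 842, against at most 24.1 for any of them in the other 19, while the B cell gene Cd79a was at 0.195. Mouse blood is rich in B cells, but their markers did not rise with the other blood cell genes in this library. This comparison covers 1 library and was chosen after the values were seen. Cd79a was also near the floor in the other 19, at most 0.593 FPKM. It therefore does not decide whether circulating blood was the source. Circulating blood, cells of blood formation in the tissue, and blood of an unusual make-up stay open.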

How the results depend on the processing

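Of the values recomputed, 1452 kept their direction and side of the threshold or stayed within 1.5 times the count, 138 kept their direction but were no longer past the threshold, 72 counts moved, 1 gene passed anew and none reversed. The fits of 20 libraries and voom were chosen after seeing the data. Of 181 named genes, the call was kept in 145 with the codes as a random block, 137 with the compared groups only, 179 with median-ratio scaling, 149 with no filter, 174 with a pseudocount of 0.1 and 180 with quantile normalization; of 85, 83 with 20 libraries and 71 with voom. These totals pool unlike comparisons. For RMC-6272 at 72 h the call was kept in 6 of 24 with the codes and 0 of 24 with the compared groups only. At 48 h it was kept in 0 of 4 with either, and for doxycycline against vehicle in 24 of 24 with either. Where a group kept 1 library, that library was assumed to vary like the other groups. The replicate numbers do not pair the samples (deviations under the same number had a median r of -0.004, and 0.002 under other numbers), and with them as a block 29 genes changed at 48 h of RMC-6272 and 0 over its time course, with the other counts within 1.5 times.

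With RMC-6272 at 24 h the count was 1858 with the codes as a random block, 4840 with 20 libraries, 4769 with voom and 1684 to 2422 without 1 replicate. At 48 h it was 1 with a pseudocount of 0.1, 0 with the codes, 2 with the compared groups only, 15 with 20 libraries, 3 with voom and 0 to 82 without 1 replicate. At 72 h it was 791 with no filter, 150 with the codes, 0 with the compared groups only, 3646 with 20 libraries, 4090 with voom and 108 to 3404 without 1 replicate. Over its time course it was 2 other genes with a pseudocount of 0.1, 32 with no filter, 0 with median-ratio scaling, 1 with quantile normalization, 46 with the codes, 0 with 20 libraries, 0 with voom and 0 to 922 without 1 replicate. For sorafenib at 4 h it was 2 with no filter, 1 with the compared groups only, 1 with 20 libraries and 0 to 1 without 1 replicate. At 24 h it was 0 with a pseudocount of 0.1, the codes, the compared groups only or voom, 11 with no filter and 0 to 1 without 1 replicate, and at 48 h 3 with no filter. Over its time course it was 0 with a pseudocount of 0.1, the codes or voom, 18 with no filter and 0 to 2 without 1 replicate. Against sorafenib, RMC-6272 gave 778 with no filter, 2304 with the codes, 2687 with the compared groups only, 2550 with 20 libraries, 2434 with voom and 1 to 906 without 1 replicate. With the compared groups only, RMC-4627 against vehicle gave 4277 and RMC-6272 against RMC-4627 3072.

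Counts without 1 replicate stayed at 6130 to 7286 for doxycycline, 6427 to 8183 for RMC-4627, 5821 to 7796 between the RMC compounds and 5551 to 7025 for RMC-6272 against doxycycline. Of 200 list calls 8 held with an estimated correlation and 99 with fry, and no list reversed. The 8 were 2 in each comparison that holds the doxycycline or RMC-4627 libraries, and no other comparison kept any. Against vehicle, fry kept 23 of 25 calls for RMC-6272 at 24 h, 4 of 25 at 48 h and 25 of 32 at 72 h. The share of called genes that were higher moved with scaling for doxycycline, from 35.4% to 45.9 (median-ratio) and 49.1% (quantile), and for RMC-4627 from 34.6% to 46.7 and 51.1%. For RMC-6272 it moved from 67.5% to 53.8 and 47.2% against RMC-4627, from 66.7% to 55.0 and 48.8% against doxycycline, and at 72 h against vehicle from 44.9% to 42.2 and 30.9%. With quantile normalization the majority turned for RMC-4627 and for RMC-6272 against RMC-4627 and doxycycline. At 72 h voom gave 786 higher and 3304 lower. The cause was not tested for any of these moves.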

Other observations

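The tests of doxycycline against RMC-4627, of the cell cycle hypothesis and of the lists and largest rises without RMC-6272 replicate 2 or without 72 h replicate 3 were chosen after the results were seen. At 24 h of RMC-6272, extracellular matrix genes rose in 5 of 30, also adjusted over the list alone (adjusted p = 0.00136, and adjusted p = 0.428 with an estimated correlation), and hepatocyte transcription factors in 4 of 16 (5 adjusted over the list alone; adjusted p = 0.00304, and adjusted p = 0.428 with an estimated correlation), among them Nr1i2, a drug sensor (2.69), Ppara (1.71) and Foxa3 (1.11). In the p53 list 4 fell and 1 rose of 23, also adjusted over the list alone, and 2 fell without RMC-6272 replicate 2 (adjusted p = 0.0293, and adjusted p = 0.428 with an estimated correlation), and the falls include Ckap2 and Gtse1, which act in mitosis. Fetal liver and tumour genes went both ways, with 2 rises, Gpc3 (2.83) and Afp, and 2 falls among 25, and were not called. Components of the mTOR pathway had 2 rises and 4 falls among 36, with Rheb at -0.64 and Ulk1 at 1.08, and were not called (adjusted p = 0.619).

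At 72 h of RMC-6272, liver endothelial genes rose in 2 of 20 (8 adjusted over the list alone; adjusted p = 4.29e-06, and adjusted p = 0.355 with an estimated correlation) and immediate early genes in 2 of 18 (9 adjusted over the list alone; adjusted p = 5.26e-05, and adjusted p = 0.355 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.60 with no member past limma's threshold and 17 of 76 at unadjusted p under 0.05 (adjusted p = 1.12e-05, and adjusted p = 0.355 with an estimated correlation). Without 72 h replicate 3, no member of these 3 lists passed in limma (4, 3 and 0 at unadjusted p under 0.05). The medians were then 0.38, 0.33 and 0.37 (camera adjusted p = 0.00527, 0.0339 and 0.0105 at the preset correlation). An estimated correlation, with which none of the 3 was called in the full fit, was not tried without that library. At 12 h the single library had Saa1 at 1700 FPKM against 2.33 ± 2.53 in vehicle, Hp at 11015 against 227 ± 278, Orm1 at 5037 against 28.4 ± 38.0, Lcn2 at 1068 against 5.96 ± 5.05 and Mthfd2 at 6.28 against 28.7 ± 3.17, genes chosen after their values were seen. Mki67 was at 8.62 and Myc at 5.92 FPKM in that library.

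Doxycycline and RMC-4627 are the groups whose values show no single-read steps, which does not show that they were made the same way, and the RMC-4627 libraries correlated at r = 0.758. Between doxycycline and RMC-4627 1675 genes differed, 880 higher and 795 lower with doxycycline, and 3621 had an unadjusted p under 0.05. No list was called by camera. The largest gap past the test was in Actr10 (4.78; 81.7 against 1.85 FPKM), with Mafk at 4.30, Fgfr1op2 at 3.84 and Dcp1a at 2.72, named after their values were seen.

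A hypothesis was that cell cycle genes return in part after 24 h of RMC-6272. All 36 G2/M genes were higher at 48 h than at 24 h, with a median difference of 1.04. Camera p, for this list alone and not adjusted over the lists as elsewhere, was 8.66e-36, and 0.00335 with an estimated correlation of 0.459. This is consistent with a partial return, but it was found and tested on the same libraries, and the times come from different samples with no vehicle at 48 h.

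Other splits of the libraries were counted for the comparisons with 3 libraries a side. With 3 against 3 there are 10 splits, too few for a share under 0.05. For RMC-6272 at 24 h 1 of the 10 gave as many genes as the real 3120, the real one, and the highest other gave 1. At 48 h it was 1 of 10, with 9 genes and 0, at 72 h 1 of 10, with 1672 and 51, and for sorafenib at 4 h 10 of 10, with 0 and 0. For the RMC-6272 time course 38 of 100 splits gave at least the real 2 genes, so chance is not excluded. The highest other gave 1227, which points to a structure of the 9 samples across the times. RMC-6272 replicate 2 at 24 h correlated with 72 h replicate 1 at r = 0.9844, above its 0.9347 and 0.9365 with its own group. Both libraries share a description code. So does 24 h replicate 3, which correlated with them at only 0.9365 and 0.947. How far the pair at r = 0.9844, or the code, accounts for the 1227 genes was not tested.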
